A study of Rattus norvegicus with 43 samples.

How the data were processed

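Gene expression was measured in the foreskin of male rat pups on the Illumina RatRef-12 beadchip, 1 array per litter and 43 arrays in all. Per the labels, pregnant Sprague Dawley rats received corn oil, or dibutyl phthalate (DBP) at 100 or 500 mg/kg/day, by gavage on gestational days 16 to 20, and the RNA was amplified and labelled with biotin. The study's design text states that 2 foreskins of a litter were pooled. Groups were taken from the sample titles, which give the age, the dose, the study and the replicate number.

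The deposited table of non-normalized values held, per the file headers, a signal intensity and a detection p-value for each of 22523 probes on each array. The signals were on a linear scale with no background subtracted, as their values showed. The second deposited table held the authors' processed intensity per probe, also on a linear scale. Within each of 3 sets of arrays (the GD20 DBP100 study, the GD20 DBP500 study and PND5) the sorted values of this table lay within 0.166% of each other at most (99th percentile 0.00832%), and they differed between the sets, so the authors' values were quantile-normalized within each study. The rank of every probe on an array was the same in both deposited tables. The submitters' processing notes, as listed with the samples, name limma and give no version.

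Values were computed here from the non-normalized signals with limma 3.58.1 in R 4.3.3. The background of each array was estimated from the detection p-values with the function nec, and an offset of 16 was added. All 43 arrays were then quantile-normalized together on the linear scale, and log2 was taken last. These steps are called neqc below. A probe was tested if its detection p-value lay under 0.05 on at least 5 arrays, the size of the smallest group, which kept 13577 probes (60.3%). A linear model with 1 mean per group was fitted to all 7 groups, the spread was moderated across probes with 5.48 prior degrees of freedom, and each comparison was read as a contrast. The p-values were adjusted by Benjamini-Hochberg within each comparison, and a probe passed at an adjusted p under 0.05. All tests were two-sided. Differences are log2 values with the standard error (SE) of the model, and spreads within a group are standard deviations (SD). A fold against a group in which no array detected the probe is given as a lower bound, computed against the detection limit of that group. The number of arrays limits the precision.

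The deposited tables pair each probe with a gene symbol where there is one: 13793 probes carried 1 symbol, 0 carried several and 8730 carried none. Of the symbols, 13757 were matched to the rat RefSeq gene table and 4 of these were updated, which left 13337 distinct symbols. No coordinates were used.

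Each exposed group was compared with the controls of its own study. The doses at PND5 were compared directly, the doses at GD20 as a difference of differences, and the ages likewise for each dose. The controls were compared between the GD20 studies and between the ages. In 27 gene lists for cell types, hormone responses, signalling pathways and metabolism, each gene was represented by its tested probe of highest mean. Of the lists, 26 held tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The number of members that pass when adjusted over the list alone is also given.

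The comparisons, the lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, with exceptions. The closing sections name the fits, tests, bounds and the amino acid list that were added or changed after results were seen. The rule named the 10 largest rises and the 10 largest falls among the probes that passed and carried 1 symbol, plus up to 4 passing members of each list. Where fewer than 10 probes passed all passing genes were named, and where 0 passed the 5 genes of smallest p. Fkbp5 and Esr1 were named whatever their result, and 4 further genes fixed in the same way are not analysed here. Placeholder symbols were skipped. The text gives a subset of the genes the rule named, smallest for the control comparisons, and the others are not reported here. List members that did not pass over all probes, and genes given as members of the amino acid response, were chosen after their values were seen.

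The pipeline was tested on simulated data with the spread of the fit to all 7 groups, drawn independently for each probe. In these, 200 probes were changed by a log2 difference of 0.5, 1 or 2. For DBP500 at GD20 data with 1 shifted list were also made. That list ranked 1 of the lists (camera adjusted p = 2.68e-27), and 0 of 25 lists left alone passed. The simulated genes of a list did not vary together. The simulation therefore cannot show how often camera calls an unchanged list of correlated genes. Variation that many probes of an array share was likewise left out. The recovery rates given below hold for independent noise and may not hold for these arrays.

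Alternatives replaced the background correction, the normalization and the set of arrays it spans, the values by the authors' own, the detection filter, the arrays in the fit, the weights of the arrays, the block, the threshold and the summary of probes per gene, and left out each array in turn. The closing section gives their effect. A chip effect could not be fitted, since the deposited tables do not name the chip of an array. Within each comparison 100 groupings of the arrays, the real one included, were counted. Scores on the leading direction of variation inside groups were computed with loadings from the arrays of the other studies, were centred within each study, and were compared by exact permutation tests over all arrangements.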

Results

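Foreskin RNA was measured in litters of rats whose mothers had received corn oil or dibutyl phthalate (DBP), a plasticizer, at 100 or 500 mg/kg/day late in gestation. On gestational day 20 (GD20) the doses were run as separate studies, with 6 control and 5 exposed litters for DBP100 and 6 control and 5 exposed litters for DBP500. On postnatal day 5 (PND5) there were 7 control, 7 DBP100 and 7 DBP500 litters. The median signal of an array lay between 102.9 and 193.2 intensity units, and 10029 to 12078 of 22523 probes were detected on an array (44.5% to 53.6%). No array repeated the values of another, as 0 were identical. The PND5 arrays fell into 2 sets by their highest signal: 15335 to 17753 units in replicates 1 to 4 and 20110 to 29459 units in replicates 5 to 7, with 4 and 3 arrays of each group.

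At the end of dosing with 500 mg/kg/day, single genes induced by amino acid shortage and by cell stress rose in the foreskin, and those of a peptide hormone and a steroid-oxidizing enzyme fell. Asns, which makes asparagine, was higher than in controls by a log2 difference of 1.45 ± 0.182 (SE; 2.74-fold, adjusted p = 9.18e-06, n = 5 and 6), and Nupr1, a stress-induced chromatin protein, by 1.5 ± 0.195 (adjusted p = 1.16e-05). Both lay above every control on 5 of 5 exposed arrays. Cck, the precursor of cholecystokinin, fell by 1.55 ± 0.243 (2.94-fold, adjusted p = 0.000377), and Cyp1b1, which oxidizes steroids and foreign compounds, fell by 0.90 ± 0.164 (adjusted p = 0.00408). Both lay below every control on 5 of 5 exposed arrays.

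Other genes that rose with DBP500 at GD20 were the lipid enzymes Scd, a fatty acid desaturase (1.0 ± 0.207, adjusted p = 0.0137), and Elovl3, a fatty acid elongase (1.18 ± 0.276, adjusted p = 0.0401), the platelet-derived growth factor receptor Pdgfra (0.85 ± 0.171, adjusted p = 0.0125) and the anion transporter Slc26a4 (1.16 ± 0.237, adjusted p = 0.0125). Adm2, a vasodilator peptide, was detected on 5 of 5 exposed and 0 of 6 control arrays and was at least 1.24-fold higher (adjusted p = 0.00141). Its DBP500 replicate 3 read 6.52 against 5.69 to 5.90 on the other exposed arrays. Mia, a secreted cartilage protein, was detected on 4 of 5 exposed and 0 of 6 control arrays and was at least 1.53-fold higher. Gprc5a, a retinoid-induced receptor, and C2cd5, a vesicle transport protein, rose by 0.92 and 0.91. Hsd11b2, which inactivates glucocorticoids, fell by 0.79 ± 0.18 (adjusted p = 0.0318), and control replicate 2 read 5.39 against 6.12 to 6.24 on the other controls. The matrix protein Ltbp2 fell by 0.86 ± 0.179 (adjusted p = 0.0139) and the smooth muscle actin-binding protein Tagln by 0.70 ± 0.153 (adjusted p = 0.0214). Further falls were found for the axon guidance ligand Slit1 (-1.04), the proteoglycan Spock1 (-1.01), the calcium-binding protein Necab2 (-0.97), the muscle dehydrogenase Dhrs7c (-0.93) and the butyrophilin Btnl7 (-1.05).

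**Figure D1:**
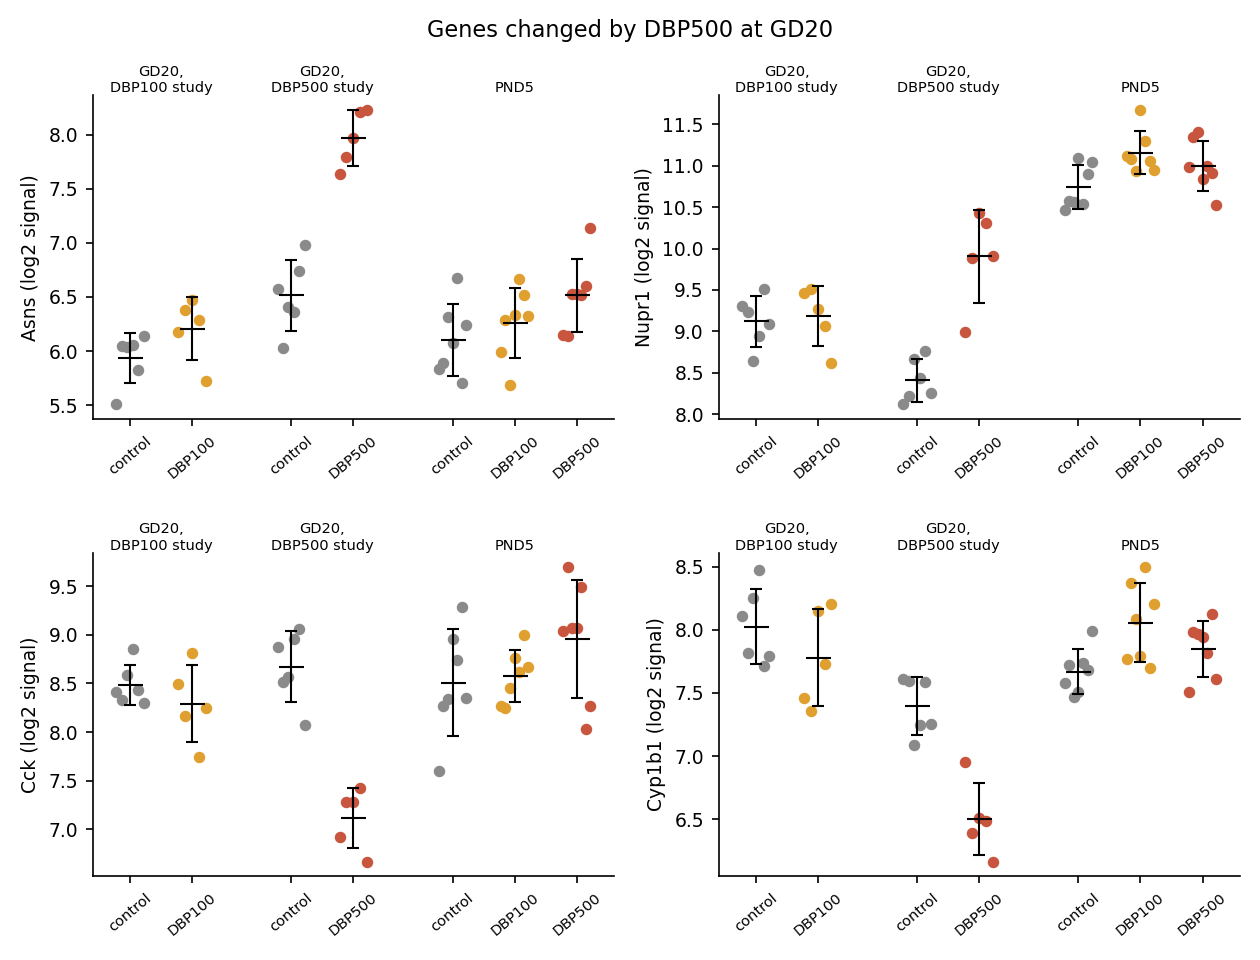
Log2 signals of Asns, Nupr1, Cck and Cyp1b1 on GD20, with each array as a point, the mean and SD of each group as bars, and controls in grey, DBP100 in orange and DBP500 in red. In the DBP500 study the mean of Asns went from 6.52 to 7.97 and that of Cck from 8.67 to 7.12.

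In all, 41 of 13577 probes passed for DBP500 at GD20, 24 higher and 17 lower, and 1003 had an unadjusted p under 0.05. The simulation at this size, with independent noise, recovered 49.3%, 89.6% and 100% of changes of 0.5, 1 and 2 on the log2 scale. The count was 22 without control replicate 4, 26 without DBP500 replicate 3 and 23 without DBP500 replicate 4. Asns, Nupr1 and Cck passed in each of 11 fits that left out 1 array and under all 12 other planned settings, and 7 of the 21 genes the rule named passed in all the fits that left out 1 array.

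For DBP500 at GD20 6 lists passed camera at its preset correlation, and 0 passed with an estimated correlation or with fry. Of 19 measured genes of differentiated epidermis, 18 stood higher and 1 lower, with a mean log2 difference of 0.34. None passed singly, 0 over all probes and 0 adjusted over the list alone (camera adjusted p = 5.05e-06; with an estimated correlation, adjusted p = 0.156). The members of smallest p were Ly6d, Sprr1a and Krt4, a membrane protein, an envelope protein and a keratin of stratified epithelium (0.40, 0.88 and 0.59). Of 11 hair follicle and sebaceous gland genes 2 passed, higher, and 2 adjusted over the list alone, both of them the lipid enzymes Scd and Elovl3, so that the mean of the list was 0.26 and its median 0.0706 (camera adjusted p = 0.0134; with an estimated correlation, adjusted p = 0.259).

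Muscle, leukocyte and nerve lists stood lower with DBP500 at GD20. Of 14 smooth muscle genes 10 stood lower, Tagln passed, and 2 passed adjusted over the list alone, the other being the intermediate filament gene Des (-0.63; camera adjusted p = 0.00557; with an estimated correlation, adjusted p = 0.175). Of 27 skeletal muscle genes 20 stood lower and 0 passed either way, with embryonic myosin Myh3 at -1.58 ± 0.705 and skeletal actin Acta1 at -1.69 ± 0.866 (camera adjusted p = 0.000857; with an estimated correlation, adjusted p = 0.472). Of 17 leukocyte and macrophage genes 15 stood lower and 0 passed over all probes. Adjusted over the list alone 2 passed, the complement gene C1qa and the macrophage gene Aif1, each at -0.45 (camera adjusted p = 0.000114; with an estimated correlation, adjusted p = 0.231). Of 12 Schwann cell and nerve genes 10 stood lower and 0 passed either way (camera adjusted p = 0.0159; with an estimated correlation, adjusted p = 0.175; without DBP500 replicate 1, camera adjusted p = 0.0829).

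At 100 mg/kg/day on GD20, 69 of the 80 probes that passed fell. Lims1, a focal adhesion adaptor, fell by 2.06 ± 0.42 (adjusted p = 0.0192, n = 5 and 6). Septin7, a cytoskeletal GTP-binding protein, fell by 1.37 ± 0.24 (adjusted p = 0.00578), and Dsc3, a desmosomal cadherin of the epidermis, fell by 1.52 ± 0.304 (adjusted p = 0.0192). Cdkn1a, the p21 inhibitor of the cell cycle, fell by 1.60 ± 0.369 (adjusted p = 0.0312). Below every control lay 3, 3, 4 and 4 of the 5 exposed arrays for these genes.

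Genes that rose with DBP100 at GD20 included the laminin receptor subunit Itga7 (0.80 ± 0.158, adjusted p = 0.0192), the secreted Wnt modulator Dkk3 (0.77 ± 0.18, adjusted p = 0.0316), the developmental transcription factor Hoxd3 (0.78 ± 0.188, adjusted p = 0.0395) and the sodium pump regulator Fxyd1 (0.51 ± 0.12, adjusted p = 0.0347). Itga7, Dkk3 and Fxyd1 lay above every control on 5 of 5 exposed arrays. The vitamin K carboxylase Ggcx rose by 1.97 ± 0.484 (adjusted p = 0.042), with 2 of 5 exposed arrays above every control. The olfactory receptor Or10ac1 rose by 0.66 (adjusted p = 0.0162) and was detected on 1 of 6 control arrays. The mannosyltransferase Tmtc3 fell by 1.75 (adjusted p = 0.0327) and the ubiquitin ligase Rc3h2 by 1.48 (adjusted p = 0.031). Utp14a, a ribosome assembly gene, fell by 1.26 on the probe that passed and stood at -0.00518 on its other probe.

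For DBP100 at GD20 80 probes passed, 11 higher and 69 lower, and 1547 had an unadjusted p under 0.05. The simulation recovered 41.8%, 88.1% and 100% of changes of 0.5, 1 and 2. The count was 121, 4 and 3 without control replicates 1, 2 and 5, and 1, 0, 1, 466 and 366 without DBP100 replicates 1, 2, 3, 4 and 5. All 18 genes the rule named lost their call without at least 1 array, and 0 passed in a fit to the 11 arrays of this comparison alone. Of 100 groupings of those arrays, the real one included, 7 gave at least as many calls. With the 12 GD20 controls pooled 25 probes passed, 20 of them higher, and 3 of the 80 were among them.

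As groups with DBP100 at GD20, 15 of 19 differentiated epidermis genes stood lower. The mean log2 difference was -0.32, 0 passed over all probes, and 1 passed adjusted over the list alone, the suprabasal keratin Krt10 (-1.19; camera adjusted p = 0.00165; with an estimated correlation, adjusted p = 0.369). Of 14 immediate-early and heat-shock genes 10 stood lower, 0 passed, and 1 passed adjusted over the list alone, the growth response factor Egr1 (-0.67; camera adjusted p = 0.0275; with an estimated correlation, adjusted p = 0.369). Endothelial genes stood higher for 9 of 11 members, with 0 past the threshold either way (camera adjusted p = 0.0275; with an estimated correlation, adjusted p = 0.369). Mast cell genes stood higher for 9 of 11 members and 0 passed. Adjusted over the list alone 2 passed, the proteases Tpsb2 (0.63) and Mcpt1 (0.47; camera adjusted p = 0.0496; with an estimated correlation, adjusted p = 0.428). The last 3 lists lost their call without some single arrays: the camera adjusted p rose to 0.125 without control replicate 2, to 0.135 without DBP100 replicate 5 and to 0.13 without DBP100 replicate 2, in that order.

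The comparison of the GD20 effects of both doses asked whether DBP500 acted differently from DBP100. Scd differed by 1.57 ± 0.293 and Nupr1 by 1.43 ± 0.275 (both adjusted p = 0.0401), each in favour of DBP500. Asns differed by 1.18 ± 0.258, Pdgfra by 1.14 ± 0.242, the redox enzyme Glrx by 1.21 and the malic enzyme Me1 by 0.90 (all adjusted p = 0.044). In favour of DBP100 differed the sodium channel subunit Scn3b (-1.20), the hormone precursor Pomc (-0.98) and the sialic acid enzyme Gne (-0.85). Adm2, the glutamate receptor subunit Gria4 and Or10ac1 passed as well, but each was detected on 0 arrays of some groups, so that part of the difference lay in the background.

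Of all probes 18 passed for the difference between the GD20 doses, 10 higher and 8 lower, and 1446 had an unadjusted p under 0.05. With the median shift 0 passed, with no detection filter 0, and in a fit to only the arrays compared 2, and 0 of the 12 genes named passed under every setting. The count lay between 0 and 126 when 1 array was left out and moved by more than 1.5 times without any of 19 of the 22 arrays. The 3 exceptions were controls 1 and 3 of the DBP100 study (14 and 27) and DBP500 replicate 5 (15), and the highest count was 126, without DBP100 replicate 4.

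For 18 of 19 differentiated epidermis genes the estimated effect at GD20 was higher with DBP500 than with DBP100, with a mean difference of 0.66, and 0 members passed over all probes and 6 over the list alone. The exposed groups lay at the same mean log2 level (8.206 with DBP100 and 8.202 with DBP500), and the difference was that between the controls of the studies (8.522 and 7.859). This list passed with the preset correlation (camera adjusted p = 1.38e-08) and with an estimated correlation (adjusted p = 0.0342). By the sign of the difference of effects, without a call over all probes, leukocyte genes (16 of 17, 3 past the threshold over the list alone, camera adjusted p = 0.000223; with an estimated correlation, adjusted p = 0.244), skeletal muscle genes (22 of 27, camera adjusted p = 0.00576; with an estimated correlation, adjusted p = 0.47), smooth muscle genes (11 of 14, camera adjusted p = 0.0302; with an estimated correlation, adjusted p = 0.244) and Schwann cell genes (10 of 12, camera adjusted p = 0.00993; with an estimated correlation, adjusted p = 0.13) stood lower with DBP500. Mast cell genes (10 of 11, camera adjusted p = 0.0302; with an estimated correlation, adjusted p = 0.411) and endothelial genes (9 of 11, camera adjusted p = 0.0433; with an estimated correlation, adjusted p = 0.328) stood lower too. Standing higher were immediate-early genes (12 of 14, camera adjusted p = 0.00576; with an estimated correlation, adjusted p = 0.244) and hair follicle and sebaceous genes (8 of 11, with Scd called, camera adjusted p = 0.0146; with an estimated correlation, adjusted p = 0.252).

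On PND5, the largest number of single genes passed for DBP500. Ada, which deaminates adenosine, rose by 1.26 ± 0.263 (2.39-fold, adjusted p = 0.00764, n = 7 and 7), from a mean log2 signal of 9.61 to 10.87. Casp14, the caspase of cornifying keratinocytes, fell by 0.95 ± 0.177 (adjusted p = 0.00284), while 12 of 19 differentiated epidermis genes stood higher and the list did not pass (camera adjusted p = 0.559; with an estimated correlation, adjusted p = 0.908). The RNA decay factor Zfp36l2 fell by 1.64 ± 0.414 (adjusted p = 0.021), the hair follicle transcription factor Trps1 fell by 1.30 ± 0.324 (adjusted p = 0.02), and Hhip, which binds hedgehog ligands, fell by 1.26 ± 0.313 (adjusted p = 0.0197). Beyond every control lay 6 of 7 exposed arrays for Ada and Casp14, and 4 of 7 for the last 3 genes.

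Further rises with DBP500 at PND5 were those of the urinary protein genes Mup4l4 (1.75 ± 0.343, adjusted p = 0.00395) and Mup4l3 (1.09 ± 0.296, adjusted p = 0.03), whose family members are close in sequence, the ribonuclease Rnase12 (1.34 ± 0.302, adjusted p = 0.0112), the allantoicase Allc (1.29 ± 0.289, adjusted p = 0.011) and the phosphatase Cdc25b (0.87 ± 0.171, adjusted p = 0.00395). The peptides Nts and Avp (1.05 and 0.97), the immune ligand Sectm1b (1.05) and the carbonic anhydrase Car2 (0.90) rose too. Avp of control replicate 6 read 6.50 against 5.10 to 5.68 on the other controls. Further falls were those of the phosphatase Dusp3 (-1.27 ± 0.236, adjusted p = 0.00284), the transcription factors Klf13 (-1.48 ± 0.346, adjusted p = 0.014) and Nfix (-1.46, adjusted p = 0.0257), the splicing factor Srsf11 (-1.17, adjusted p = 0.00575) and the matrix gene Fbn2 (-0.97 ± 0.23, adjusted p = 0.0155). Wdfy1, Cmip and Kdsr, an endosomal, an adaptor and a sphingolipid gene, stood at -1.51, -1.25 and -1.20. Control replicate 1 lay apart from the other controls for Zfp36l2 (5.92 against 7.55 to 8.37), Trps1, Nfix, Cmip, Srsf11 and Fbn2.

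**Figure D2:**
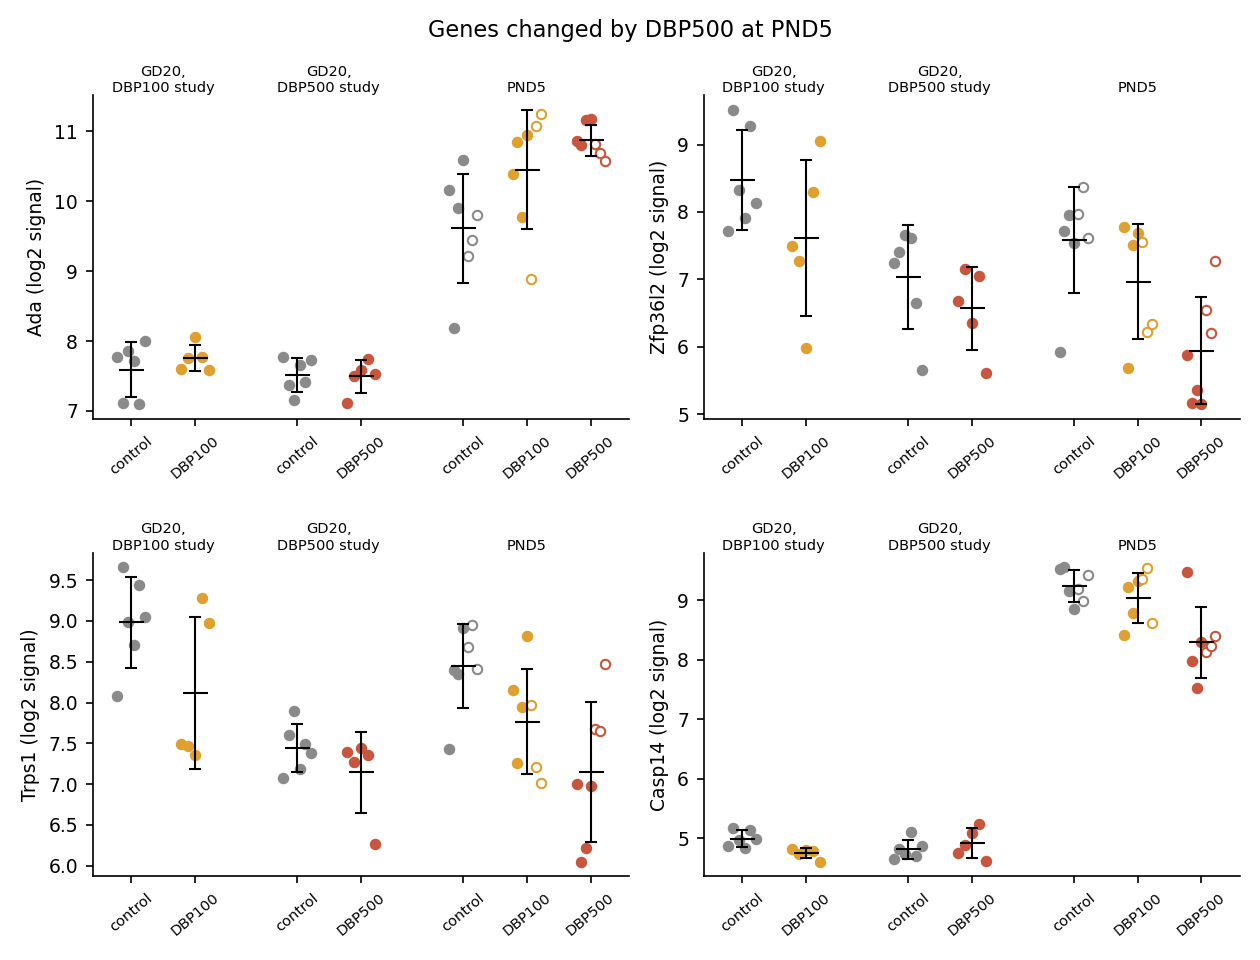
Log2 signals of Ada, Zfp36l2, Trps1 and Casp14 on PND5, with each array as a point (open for replicates 5 to 7), the mean and SD of each group as bars, and controls in grey, DBP100 in orange and DBP500 in red. The mean of Ada was 9.61 in controls, 10.45 with DBP100 and 10.87 with DBP500, and that of Casp14 was 9.24 in controls and 8.29 with DBP500.

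For DBP500 at PND5 498 probes passed, 202 higher and 296 lower, and 2486 had an unadjusted p under 0.05. The simulation recovered 50.7%, 89.6% and 100% of changes of 0.5, 1 and 2. The count was 248 without control replicate 4, and 256, 190 and 309 without DBP500 replicates 2, 3 and 4. Ada, Allc, Casp14, Cdc25b, Dusp3 and Rnase12 passed in each of 14 fits that left out 1 array and under every planned setting that held their probe, and 12 of the 29 genes the rule named passed in all the fits that left out 1 array. With each array shifted to the same median in place of quantile normalization 34 probes passed, all 34 among the 498.

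Between the PND5 array sets the effects of DBP500 correlated at r = 0.303 over all tested probes. Of the 498 probes, which were chosen from both sets together, 490 had the same sign in both (98.4%). Ada differed by 1.29 in replicates 1 to 4 and by 1.21 in replicates 5 to 7, Casp14 by -0.95 in both, Zfp36l2 by -1.90 and -1.30, and Trps1 by -1.71 and -0.75. Klf13 (-2.45 and -0.20) and Hhip (-1.95 and -0.34) stood further from controls in replicates 1 to 4, and the contrast between the sets passed for 5 probes in all. In replicates 1 to 4 alone 114 probes passed, and in replicates 5 to 7 alone 0 passed (limma; 1356 with an unadjusted p under 0.05).

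Scores on the leading direction of variation inside groups, taken from the GD20 arrays, fell at PND5 from 6.38 ± 4.51 (SD, n = 7) in controls to -0.11 ± 3.99 with DBP100 and -6.27 ± 5.59 with DBP500 (exact permutation p = 0.0186 and p = 0.00175). With this score as a covariate 0 of the 498 probes passed (limma; 1042 with an unadjusted p under 0.05). A median share of 0.454 of their differences was left, the median SE went from 0.153 to 0.226, 418 kept their sign, and Zfp36l2, Trps1 and Hhip changed sign (0.15, 0.27 and 0.54) while Ada and Casp14 kept theirs (0.73 and -0.81). At GD20 the score was 4.30 ± 8.60 (SD, n = 6) in DBP100-study controls and -5.16 ± 7.61 (n = 5) with DBP100 (exact permutation p = 0.0996), and with it as a covariate 0 of 80 probes passed (340 with an unadjusted p under 0.05). For DBP500 at GD20 the scores differed by 0.0375 (exact permutation p = 0.991), and 40 probes passed, Asns, Nupr1 and Cck among them. A score on which the groups hardly differ cannot move their difference, so this fit decides nothing about shared variation. With loadings from the PND5 arrays alone the scores differed by -2.7 ± 1.01 (SE), and 8 probes passed, with a median share of 1 of the differences of the 41 left and a median SE of 0.22 in place of 0.166. Asns stood at 1.15 (adjusted p = 0.0334), Nupr1 at 1.29 (adjusted p = 0.0278) and Cck, which did not pass, at -1.37 (adjusted p = 0.104).

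**Figure D3:**
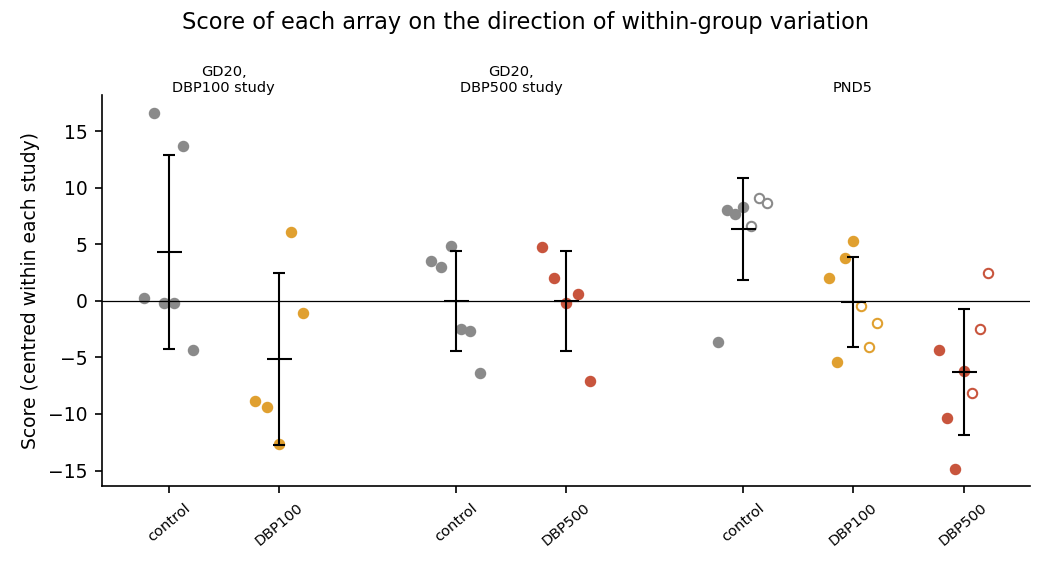
Score of each array on the leading direction of variation inside groups, by group and centred within each study; points are arrays, open for PND5 replicates 5 to 7, and bars give mean and SD. PND5 controls averaged 6.38 and PND5 DBP500 litters -6.27.

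List members that changed with DBP500 at PND5 went several ways, and no list passed camera (0 of 26; lowest adjusted p = 0.109; with an estimated correlation, lowest adjusted p = 0.555). Fry passed 2 lists, both higher: fatty acid oxidation (adjusted p = 0.0324) and sex steroid receptors and metabolism (adjusted p = 0.0456). Of 14 smooth muscle genes 1 passed, the myogenic co-activator Myocd (-0.87 ± 0.199, adjusted p = 0.0127), and 4 adjusted over the list alone, all lower. Of 26 matrix and fibroblast genes 1 passed, Fbn2, and 4 adjusted over the list alone, all lower, with the collagen-binding proteoglycans Dcn (-0.31) and Lum (-0.39) among them. Of 26 genes of fatty acid oxidation 2 passed, higher: catalase Cat (0.70 ± 0.191, adjusted p = 0.0297) and the thiolase Acaa2 (0.61 ± 0.173, adjusted p = 0.0372). Adjusted over the list alone 3 passed (camera adjusted p = 0.161; with an estimated correlation, adjusted p = 0.555). The retinoid carrier Crabp1 (0.48) and globin Hbb (0.70) rose, and the fatty acid transporter Cd36 (-0.50) fell.

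At 100 mg/kg/day, litters at PND5 differed from controls in few single genes. The membrane protein Tmem33 rose by 0.62 ± 0.111 (adjusted p = 0.0245, n = 7 and 7) and the copper chaperone Cox17 by 0.56 ± 0.121 (adjusted p = 0.0464). The deubiquitinase Zup1 (-0.58 ± 0.113), the trafficking adaptor Gga3 (-0.52) and the Ras regulator Nf1 (-0.52, detected on 1 of 7 exposed and 4 of 7 control arrays) fell, as did Lcat, which esterifies plasma cholesterol (-0.56 ± 0.12, adjusted p = 0.0464). These genes were chosen from both array sets together. In replicates 1 to 4 and in replicates 5 to 7 alone none of them passed, with Tmem33 at 0.69 and 0.53 (adjusted p = 0.955 and 0.192) and Zup1 at -0.66 and -0.49 (adjusted p = 0.945 and 0.264).

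In all, 11 probes passed for DBP100 at PND5, 3 higher and 8 lower, and 1418 had an unadjusted p under 0.05. The simulation recovered 47.8%, 92.5% and 98.5% of changes of 0.5, 1 and 2. Without control replicates 1, 2, 4 and 5 the count was 24, 1, 6 and 4, and without DBP100 replicates 1, 4, 5, 6 and 7 it was 71, 33, 18, 1 and 0. Of 100 groupings, the real one included, 7 gave at least as many calls. The doses at PND5, compared with the same 7 controls, shared 8 calls, 3 higher and 5 lower, with Zup1, Gga3, Cox17, Tmem33 and Lcat among them. Across probes, which are not independent replicates, the effects of both doses correlated at r = 0.659, where shared controls alone gave 0.50 in simulation and separate controls gave a median of 0.309.

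As groups with DBP100 at PND5, 12 of 14 inflammation and interferon genes stood higher, 0 passed over all probes, and 3 passed adjusted over the list alone: the immunoproteasome gene Psmb8 (0.81), the calprotectin gene S100a8 (0.92) and the cytokine Il1b (0.99). The camera adjusted p was 0.00026 (with an estimated correlation, adjusted p = 0.498; without DBP100 replicate 5, camera adjusted p = 0.276), and the mean difference was 0.19 in replicates 1 to 4 and 1.05 in replicates 5 to 7. Leukocyte genes stood higher for 15 of 17, 0 passed, and 1 passed adjusted over the list alone, the scavenger receptor Cd163 (0.76; camera adjusted p = 0.00026; with an estimated correlation, adjusted p = 0.498; without DBP100 replicate 5, camera adjusted p = 0.136). Their mean was 0.10 and 0.47 within the array sets. Adipocyte genes stood higher for 12 of 14 with 0 past the threshold either way (camera adjusted p = 0.00655; with an estimated correlation, adjusted p = 0.498; without DBP100 replicate 5, camera adjusted p = 0.136). Their mean was 0.36 and 0.26 within the array sets.

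Between the doses at PND5, the polarity kinase Prkci was lower with DBP500 than with DBP100 (-0.71 ± 0.135, adjusted p = 0.0336, n = 7 and 7), the carboxypeptidase Cpm was lower (-0.93 ± 0.191, adjusted p = 0.038) and the cell cycle factor E2f1 was higher (0.59 ± 0.12, adjusted p = 0.038). These were the genes with a symbol among 7 probes that passed, 2 higher and 5 lower (1226 with an unadjusted p under 0.05). The simulation recovered 46.3%, 97% and 98.5% of changes of 0.5, 1 and 2. The count was 12, 0, 0, 14 and 14 without DBP100 replicates 2, 4, 5, 6 and 7, and 1 and 0 without DBP500 replicates 3 and 4. Adipocyte genes stood lower for 11 of 14 (camera adjusted p = 0.00648; with an estimated correlation, adjusted p = 0.518), as did hair follicle and sebaceous genes for 9 of 11 (camera adjusted p = 0.01; with an estimated correlation, adjusted p = 0.518) and inflammation genes for 11 of 14 (camera adjusted p = 0.01; with an estimated correlation, adjusted p = 0.709). Without DBP100 replicate 5 the camera adjusted p was 0.102 for the first and second of these, and the mean of the inflammation genes turned to 0.0417 (camera adjusted p = 0.955). Within the array sets the means were -0.13 and -0.50 for adipocyte genes, -0.36 and -0.14 for hair follicle genes, and 0.11 and -1.10 for inflammation genes.

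**Figure D4:**
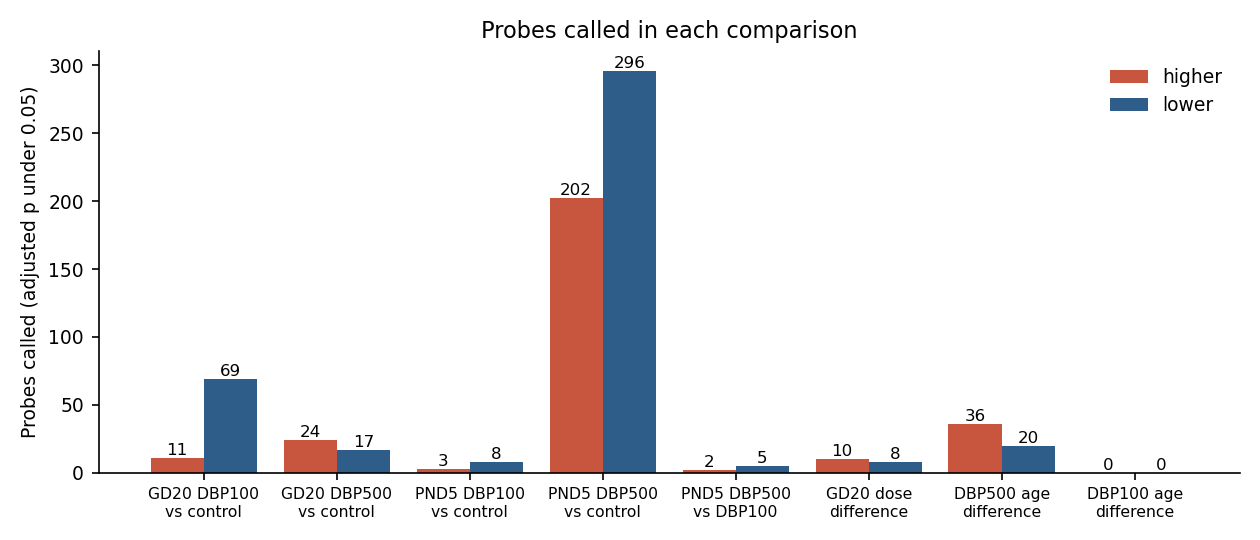
Number of probes with an adjusted p under 0.05 in each comparison of DBP with control or of DBP effects, split into higher and lower. DBP500 at PND5 had 202 higher and 296 lower, and DBP100 at GD20 had 11 higher and 69 lower.

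The estimated effect of DBP500 differed between the ages for single genes, as tested by the difference of differences. Age and study are confounded in this comparison. The effect on Cck at GD20 minus that at PND5 was -2.0 ± 0.324 (adjusted p = 0.00315), with effects of -1.55 and 0.45 at the ages, and that on Cyp1b1 -1.08 ± 0.219 (adjusted p = 0.0241). Allc (-2.03 ± 0.436, adjusted p = 0.0253), Spock1 (-1.44), Slit1 (-1.39), Dhrs7c (-1.13), the placental growth factor Pgf (-1.54) and the growth factor Gdf10 (-1.38) differed in the same direction. Nupr1 (1.24 ± 0.26, adjusted p = 0.0253), Asns (1.04 ± 0.243, adjusted p = 0.0385), Scd (1.14), Pdgfra (1.07) and C2cd5 (1.25, detected on 1 of 6 GD20 controls) differed the other way, as did the ciliary gene Tmem67 (1.22, adjusted p = 0.017, detected on 1 of 6 GD20 controls), the hormone precursor Gnrh1 (1.27) and the chromatin protein Hmgn3 (1.12).

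For this age difference 56 probes passed, 36 higher and 20 lower, and 1744 had an unadjusted p under 0.05. The count was 37, 31, 14 and 29 without DBP500-study controls 1, 2, 4 and 5, and 20, 24, 23 and 11 without GD20 DBP500 replicates 1, 2, 3 and 4. It was 33 and 30 without PND5 controls 2 and 4, and 37, 29, 31 and 98 without PND5 DBP500 replicates 2, 3, 5 and 7. Among the 20 genes the rule named, 6 passed in all 25 fits that left out 1 array. Only Cck and Tmem67 also passed under every planned setting that held their probe. Nupr1 passed in 23 of the 25 fits, Gnrh1 in 13, Asns in 10, Dhrs7c in 8 and Scd in 6. The estimated effect of DBP500 lay lower at GD20 than at PND5 for 16 of 17 leukocyte genes, of which 0 passed over all probes and 3 over the list alone (camera adjusted p = 0.00186; with an estimated correlation, adjusted p = 0.576), and for 23 of 27 skeletal muscle genes, of which 0 passed either way (camera adjusted p = 0.0246; with an estimated correlation, adjusted p = 0.748; without DBP500-study control 1, camera adjusted p = 0.134).

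For the difference between the ages in the effect of DBP100 0 probes passed with limma, the smallest adjusted p was 0.185, and 1156 had an unadjusted p under 0.05. The count was 17 without GD20 DBP100 replicate 4 and 3 without PND5 DBP100 replicate 1. The genes of smallest p, which did not pass, included the kinase Dclk2 (1.0, adjusted p = 0.185) and Lcat (0.76). In lists, with 0 members called, the estimated effect of DBP100 lay lower at GD20 than at PND5 for 17 of 19 epidermis genes (camera adjusted p = 0.00216; with an estimated correlation, adjusted p = 0.227), 13 of 14 immediate-early genes (camera adjusted p = 0.00298; with an estimated correlation, adjusted p = 0.227) and 13 of 14 inflammation genes (camera adjusted p = 0.00931; with an estimated correlation, adjusted p = 0.422; without PND5 DBP100 replicate 5, camera adjusted p = 0.389). It lay higher for 9 of 11 endothelial genes (camera adjusted p = 0.00541; with an estimated correlation, adjusted p = 0.227).

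DBP lowers fetal testosterone production, so hormone-responsive and genital development genes were examined as lists. Of 23 measured androgen-responsive genes, 1 was called lower with DBP100 at GD20, Cdkn1a, which passed in 6 of 11 fits that left out 1 array. Its level was 3.58-fold lower in the controls of the DBP500 study than in those of the DBP100 study. With DBP500 at GD20 1 was called higher, the differentiation gene Ndrg1 (0.60 ± 0.138, adjusted p = 0.0334), which passed in 2 of 11 such fits. With DBP100 at PND5 0 were called. With DBP500 at PND5 1 was called lower, the co-activator gene Cited2 (-0.40, adjusted p = 0.0379), which passed in 6 of 14 such fits. Adjusted over the list alone 1, 3, 0 and 3 passed, and the camera adjusted p was 0.242, 0.812, 0.966 and 0.858 in that order (with an estimated correlation, adjusted p = 0.49, 0.922, 0.979 and 0.956). Fkbp5, a chaperone gene induced by androgens and glucocorticoids, did not pass at either dose: 0.18 ± 0.143 and -0.43 ± 0.143 at GD20 and 0.03 ± 0.126 and 0.20 ± 0.126 at PND5 for DBP100 and DBP500 (adjusted p = 0.709, 0.299, 0.968 and 0.419). The estrogen receptor gene Esr1 was not tested, since its probe was detected on 0 arrays.

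Genes of genital tubercle and urethral development passed in 1 of 21 cases with DBP500 at PND5, Hhip, and in 0 cases in the other comparisons of DBP with control (camera adjusted p = 0.091, 0.369, 0.995 and 0.53 in the same order). Sex steroid receptor and metabolism genes had 1 call among 13, Hsd11b2 with DBP500 at GD20, which passed in 3 of 11 fits that left out 1 array (camera adjusted p = 0.39, 0.865, 0.275 and 0.167). With DBP500 at PND5 11 of the 13 stood higher and the list passed fry (adjusted p = 0.0456) but not camera with an estimated correlation (adjusted p = 0.555). Estrogen-responsive genes had 0 calls among 11 in these comparisons (camera adjusted p = 0.202, 0.99, 0.241 and 0.815). Over all comparisons, 14 of 26 lists passed camera in none.

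The GD20 controls of the studies, which carry the same label, differed in 2991 probes (1402 higher and 1589 lower in the DBP500 study; 4699 with an unadjusted p under 0.05). The adipogenic receptor Pparg (1.46 ± 0.26, adjusted p = 0.000102) and Ggcx (2.34 ± 0.461, adjusted p = 0.000335) were higher in the DBP500 study, and the interleukin-4 signal transducer Stat6 (-1.94 ± 0.221, adjusted p = 1.15e-07) and Cdkn1a (-1.84 ± 0.352, adjusted p = 0.00023) were lower. Of 19 differentiated epidermis genes 11 were called lower, 12 adjusted over the list alone, with cornified envelope gene Cnfn at -1.59 and Krt10 at -1.41 (camera adjusted p = 7.98e-07; with an estimated correlation, adjusted p = 0.0957). With each array shifted to the same median the median of all probes was 0.15, and 2351 were called higher and 1090 lower.

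In controls, PND5 foreskins differed from GD20 foreskins in 8368 probes (3624 higher and 4744 lower; 8815 with an unadjusted p under 0.05), with age and study confounded. Hair and cornification genes were higher at PND5: the hair root keratin Krt25 was at least 271-fold higher, Casp14 at least 12.9-fold, and the inner root sheath keratin Krt27, the histidine enzyme Hal, the epidermal protease Klk7 and the envelope precursor Sbsn differed by 7.75, 6.34, 5.2 and 4.22. Muscle genes Ckm, Myl1 and Tnni2, a creatine kinase, a myosin light chain and a troponin, differed by 5.18, 4.01 and 3.72, and adipocyte genes Cebpa and Fabp4 by 3.36 and 2.70. Lower at PND5 were the erythroid chaperone Ahsp (-4.51), embryonic globin Hbe1 (at least 5.09-fold), mast cell protease Tpsb2 (-1.83) and Fkbp5 (-1.73). So were the mitotic genes Plk1 (-2.11), Ube2c (-1.64) and Cdk1 (-0.81).

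By list, 18 of 19 differentiated epidermis genes stood higher in PND5 controls and 16 were called (camera adjusted p = 5.56e-12; with an estimated correlation, adjusted p = 0.00551). Skeletal muscle genes stood higher for 25 of 27, 22 of them called (camera adjusted p = 3.24e-07; with an estimated correlation, adjusted p = 0.321), and 11 of 14 adipocyte genes were called higher (camera adjusted p = 0.000325; with an estimated correlation, adjusted p = 0.321). Of 26 proliferation genes 18 were called lower and 3 higher (camera adjusted p = 0.00447; with an estimated correlation, adjusted p = 0.356). Hair follicle genes were called higher in 6 cases and lower in 2 (camera adjusted p = 0.00447; with an estimated correlation, adjusted p = 0.321). With each array shifted to the same median the median of all probes was -0.28 in place of -0.09, and 2576 were called higher and 6302 lower.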

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

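The tests of the shared direction were chosen after the result was seen, and those of the epidermis genes were fixed before it, apart from 1 bound named below. The scores on the direction along which arrays vary inside the groups of the other studies differed from controls for DBP500 at PND5 (exact permutation p = 0.00175) and did not pass for DBP100 at GD20 (exact permutation p = 0.0996). With the score as a covariate 0 of 498 calls stayed for PND5 DBP500, fewer than with 98 of 99 shuffled scores, with a median share of 0.454 of the differences left, the median SE up from 0.153 to 0.226 and 418 of 498 signs kept, which is consistent with variation between arrays that is shared across studies as part of the cause. The first bound asked for fewer calls than any shuffled score and was reworded after 1 of 99 also left 0. For GD20 DBP100 0 of 80 stayed, but so did 0 with 24 of 99 shuffled scores, and this remains open. The PND5 array sets hold equal numbers of each group, so a fit with the set as a block, in which 494 of 498 calls stayed, could not move the group differences and decides nothing, and whether DBP itself moves tissue along this direction is open, with scores at GD20 of -8.2 ± 4.41 for DBP100 and -2.70 ± 1.01 for DBP500 from their controls when loadings come from PND5.

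Differentiated epidermis genes stood higher with DBP500 and lower with DBP100 at GD20 (with an estimated correlation, adjusted p = 0.156 and 0.369) and differed between the doses by 0.659, with the exposed groups at one level (8.202 and 8.206) and the controls of the studies apart (7.859 and 8.522), the cause of which was not tested. For DBP500 these genes moved 11.2 ± 4.97% along the age change and all other probes 0.203 ± 1.38%, a difference of 11 ± 5.15 (SE). The SE of this difference combined both errors as if independent, though both came from the same arrays. The narrow margin against an older stage of the DBP500 litters rests on this SE and did not exclude such a stage. Age and study are also confounded in the age change. For DBP100 (-12.3 ± 3.49% and -8.93 ± 3.36%) a younger stage could not be excluded either. A change in the share of epidermis in the tissue piece could not be excluded for either dose, with the basal epidermis genes at 0.103 ± 0.0293 for DBP500 and -0.146 ± 0.0696 for DBP100. The bound fixed first used the error of the basal list alone and would have excluded this for both doses. It was changed after the result because it left out the error of the differentiated list, such as 0.143 for DBP500. The changed bound combined the errors of both lists as if independent. The difference between the lists was not formed on each array, so the bound cannot decide the question.

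Single arrays lay apart from the rest of their group in 12 of 177 groups of values tested, where chance gives about 1 in 20. Control replicate 6 of the GD20 DBP100 study read 10.4 for Fkbp5, the others 11 to 11.2. In the GD20 DBP500 study DBP500 replicate 3 read 6.52 for Adm2, control replicate 5 read 5.54 for Gprc5a (4.70 to 4.82 on the others), and control replicate 2 read 5.39 for Hsd11b2. At PND5 control replicate 6 read 6.50 for Avp. PND5 control replicate 1 read 5.92 for Zfp36l2, 8.50 for Nfix, 7.43 for Trps1, 8.15 for Cmip, 10.1 for Srsf11 and 9.46 for Fbn2, and its score was -3.68, where the other controls had 6.58 to 9.08.

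The effect of DBP at GD20 differed between the doses for Scd (1.57), Nupr1 (1.43), Asns (1.18) and Pdgfra (1.14). The model also gave 1.07 for Adm2 and -0.849 for Or10ac1, which hold background and are no measured sizes, since Adm2 was detected on 0 of 6 controls and Or10ac1 on 0 of 11 arrays of the DBP500 study. The effect of DBP500 differed between the ages for C2cd5 (1.25), Nupr1 (1.24), Scd (1.14), Pdgfra (1.07), Asns (1.04) and Zup1 (0.704), and for Allc (-2.03), Cck (-2.0), Spock1 (-1.44), Slit1 (-1.39), Dhrs7c (-1.13) and Cyp1b1 (-1.08). For Mia and Adm2, both detected on 0 of 6 GD20 controls, the model gave 0.987 and 0.957, which likewise hold background. The cause of these differences was not tested, and age and study are confounded in those between the ages.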

How the results depend on the processing

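The fits limited to PND5 replicates 1 to 4 or 5 to 7, the fit with these array sets as a block, those with the score and those without arrays chosen by score were added after the results were seen, and all others were fixed before. Counts are of probes called, with the groups in the order they are named. A chip could not be used as a block, since the deposited tables do not name it.

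Without background correction 0 probes passed between the PND5 doses and 7 for the GD20 dose difference. With the median shift 18 passed for DBP500 at GD20, 0 for DBP100 at PND5, 34 for DBP500 at PND5, 0 between the PND5 doses, 0 for the GD20 dose difference and 4 for the DBP500 age difference (1 higher and 3 lower). With neqc inside each study 4 passed for DBP100 at PND5. With the authors' values 152 passed for DBP100 at GD20, 0 for DBP100 at PND5 and 0 between the PND5 doses. With no detection filter these were 44 for DBP100 at GD20, 2 between the PND5 doses and 0 for the GD20 dose difference. Among probes detected on every array compared 31 passed for DBP100 at GD20, 22 for DBP500 at GD20, 3 between the PND5 doses, 1931 for the GD20 controls and 5354 for the control ages.

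Fitted to only the arrays compared, 0 passed for DBP100 at GD20, 0 for DBP100 at PND5, 128 for DBP500 at PND5 (32 higher and 96 lower), 0 between the PND5 doses and 2 for the GD20 dose difference. With the replicate number as a block 165 passed for DBP100 at GD20, 24 for DBP500 at GD20, 0 for DBP100 at PND5 and 272 for DBP500 at PND5. In that fit 0 passed between the PND5 doses, 0 for the GD20 dose difference and 29 for the DBP500 age difference. Arrays were not paired in the main fit. The most correlated array of another group had the same number for 1 of 10 arrays in the GD20 DBP100 study. This held for 4 of 10 in the GD20 DBP500 study and 3 of 21 at PND5. With array weights 1118 passed for DBP100 at GD20, 197 for DBP500 at GD20, 24 for DBP100 at PND5, 0 between the PND5 doses, 564 for the GD20 dose difference, 264 for the DBP500 age difference and 92 for the DBP100 age difference.

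With a 1.5-fold bound 3 passed for DBP100 at PND5, 259 for DBP500 at PND5, 1484 for the GD20 controls and 4645 for the control ages. Averaged per symbol 35 passed for DBP100 at GD20, 7 for DBP100 at PND5, 269 for DBP500 at PND5, 1 between the PND5 doses, 37 for the DBP500 age difference, 1 for the DBP100 age difference and 1962 for the GD20 controls. With the GD20 controls pooled 25 passed for DBP100 and 106 for DBP500. Of 37 list calls by camera 2 stayed with an estimated correlation.

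In PND5 replicates 1 to 4 alone 2, 114 and 4 passed for DBP100, DBP500 and between the doses, and in replicates 5 to 7 alone 0, 0 and 0. With the score as a covariate 2, 0 and 0 passed in the same order, and 0 for DBP100 at GD20. With the score from PND5 loadings as a covariate 8 passed for DBP500 at GD20, with a median share of 1 of the differences of the 41 calls left and the median SE up from 0.166 to 0.22, though some differences shrank, such as that of Scd to 0.724. Without both controls of highest score 1 passed for DBP100 at GD20, and without the lowest score of each group 26 passed for DBP500 at GD20. With the score as a covariate the differences for DBP500 at PND5 turned for Zfp36l2 (0.149), Wdfy1 (0.684), Klf13 (0.446), Nfix (0.945), Trps1 (0.272), Hhip (0.537), Cmip (0.815), Kdsr (0.396), Srsf11 (0.258) and Fbn2 (0.246).

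With 1 array left out the counts ran from 0 to 466 for DBP100 at GD20, 22 to 40 for DBP500 at GD20, 0 to 71 for DBP100 at PND5, 190 to 730 for DBP500 at PND5, 0 to 14 between the PND5 doses, 0 to 126 for the GD20 dose difference, 11 to 98 for the DBP500 age difference and 0 to 17 for the DBP100 age difference. The GD20 controls gave 2466 to 2824 and the control ages 8060 to 8354. The mean of the inflammation list between the PND5 doses ran from -0.499, without DBP100 replicate 1, to 0.0417, without DBP100 replicate 5, where it turned.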

Other observations

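The list of amino acid response genes was written after Asns was seen among the calls and its tests against the shared variation were chosen after the result, while the test of its uncalled members was fixed before that test was run. Beside Asns, Nupr1 and Adm2, DBP500 at GD20 raised the serine enzyme Psph (0.65 ± 0.126, adjusted p = 0.00821), the stress transcription factor Atf5 (0.71 ± 0.166, adjusted p = 0.0385) and the tRNA synthetases Cars1 (0.60 ± 0.133, adjusted p = 0.0235) and Lars1 (0.56 ± 0.104, adjusted p = 0.00408). These make 7 of 44 measured genes of the response to amino acid shortage.

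Of the 37 genes outside the calls 33 stood higher, with a mean of 0.21 (camera with an estimated correlation, p = 8.06e-06). The rise was thus not limited to the called genes. This test cannot tell a shortage of amino acids from another stress that raises the same genes. The same 37 genes had means of 0.0191 with DBP100 at GD20, 0.0264 with DBP100 at PND5 and 0.0842 with DBP500 at PND5, where 24 stood higher (camera p = 0.0413 at the preset and 0.115 at an estimated correlation; fry p = 0.00697) and the transporter Slc7a5 (0.53 ± 0.153, adjusted p = 0.0429) and the stress gene Herpud1 (0.45 ± 0.109, adjusted p = 0.0173) passed. Variation shared across studies stays open: with the score from PND5 loadings as a covariate, a test chosen last and whose bound on the differences was added after its count was seen, 2 of the 7 called genes passed and a median share of 0.863 of their differences was left, and the median SE of the calls went from 0.166 to 0.22. With the median shift 2 of the 7 passed and with the authors' values 6, but a median share of 1.12 and 0.925 of their differences was left and the median SE was 0.208 and 0.0938 in place of 0.165, and the genes outside the calls kept means of 0.261 and 0.173 with 33 and 32 above 0 (estimated correlation, p = 0.0605 and p = 1.8e-06), so the lost calls do not point to the normalization as the source, which is not excluded either. Not all members of the list moved with DBP500 at GD20. Of the 37 genes outside the calls 4 stood lower. The listed genes Trib3 (0.17 ± 0.146), Chac1 (0.194 ± 0.183), Ddit3 (0.0897 ± 0.139) and Atf3 (0.17 ± 0.265) stood near their controls and did not pass. As a hypothesis, fetal foreskin at 500 mg/kg/day may respond to a shortage of amino acids, which measured amino acids could test.

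Regrouping the arrays of a comparison tested whether chance could give as many calls. Counting the real grouping, chance could not be excluded for DBP100 at GD20 (7 of 100 groupings with at least 80 calls, highest other 642), DBP100 at PND5 (7 with at least 11, highest 46) and the doses at PND5 (9 with at least 7, highest 260). For the DBP100 age difference, with 0 calls, all 100 groupings had at least as many (highest 35), which tests nothing. Only the real grouping gave as many calls for DBP500 at GD20 (41, highest other 9) and at PND5 (498, highest other 197). The same held for the GD20 controls (2991, highest other 916) and the control ages (8368, highest other 4857). A share of 0.01 is the smallest that 100 groupings can give, so chance was unlikely in these but not excluded. For the GD20 dose difference (4 with at least 18, highest 91) arrays were regrouped across both studies, whose controls differ. This cannot decide whether chance gave a difference between the effects. For the DBP500 age difference (1 with 56, highest 2) exposure was regrouped inside each age. That tests for no effect at either age, and not for equal effects at both. Some other groupings called several times the real count: 642 for DBP100 at GD20, 260 between the PND5 doses and 91 for the GD20 dose difference. Structure among the samples could give such counts, which was not tested.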
